A study of Mus musculus with 12 samples.

How the data were processed

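RNA was taken from 3 cell types grown from the bone marrow of C57BL/6J mice aged 6 to 8 weeks, with 4 replicates of each. Per the labels' protocols, macrophage and osteoclast precursors were expanded for 5 days in M-CSF (100 ng/ml), differentiation lasted 8 to 10 days, and osteoclast cultures were treated with Accutase to remove cells with a single nucleus. Libraries were made with a stranded mRNA kit, per the labels' protocols, and read as single reads of 50 bases in 1 HiSeq lane, per the series' design text. The labels' well numbers name dendritic cells in 2 places and osteoclasts in none, and were not used. Per the submitters' processing notes the tools were bcl2fastq, Bowtie2, TopHat2, Cufflinks 2.1.1 and DESeq2 2.13 with the GRCm38 build. Their roles and order, the annotation and the strand setting of the counting are not given in the sources used here.

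The only file is a table of the authors' comparisons of 46072 Ensembl genes. Per the file headers it holds, for each pair of cell types, the authors' mean of each, a log2 fold change, a p-value and an adjusted p-value, and marks genes as significant. The means are counts divided by a size factor and averaged by the authors over 4 libraries, which follows from the values themselves. The deposited log2 fold changes lie closer to 0 than the ratio of the means for low genes. Which of them lies nearer the true change of those genes was not tested. The deposited p-values were taken as two-sided and from a Wald test, which is an inference: the standard error given beside a fold change is the fold change divided by the normal quantile of its p-value. Where the authors' p is listed as 0, no standard error can be given. A symbol matched 45138 identifiers and 934 had none; coordinates are from GENCODE M21 on GRCm38, which may differ from the annotation the authors used.

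The planned tests on counts per library did not apply, because the table has means and no column per library: the calls are the authors' own, at adjusted p under 0.05. A filter the authors applied leaves genes with a p-value but no adjusted p. Apart from Lyz2, given as the most abundant gene, genes named in the text follow a rule fixed before the data were examined, and a gene it names may be given in any comparison. Per comparison it takes the 6 largest and 6 smallest fold changes among called genes with at least 10 CPM in the higher cell type, leaving out Gm, Rik, ribosomal protein and mitochondrial symbols. It adds up to 4 members of each gene list, the 2 with the smallest p in each direction, or the 2 highest members of a list with none called. Every tubulin tested, 6 genes per cell type higher than both others, 8 label markers, Xist and 4 Y-linked genes complete it. The part of the rule asking that libraries not overlap could not be applied. The 25 lists of pathways and cell functions and the 10 lists of other cell types were also fixed beforehand. Each was tested with limma 3.58.1 (camera, inter-gene correlation 0.01, at least 3 genes) on the signed normal quantiles of the authors' p-values, with adjustment over lists and comparisons together. An estimated correlation was not run, since the table gives no values per library for high genes. A correlation of 0.05 was run instead, and calls lost with it are given beside them. The list test was tried on simulated data for osteoclasts against macrophages, with 200 genes raised among 17822 in 50 rounds. The raised genes were drawn from lists with at least 10 tested members. With them raised, 68.4% of all 35 lists were called, a share that counts the smaller lists too. With no gene raised, 0.0571% were called. The simulated values were standard normal, with 3 added for raised genes, and independent between genes. The real values spread more widely, with 5216 of the 17822 genes called. The trial covers neither that spread nor correlated genes.

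Overlap of calls between comparisons that share a cell type was set beside 200 draws of unchanged groups and beside independent lists. Because each mean is built from whole reads of 4 libraries, each divided by its size factor, whole reads per library were recovered for genes with a mean of at most 500, a limit chosen after seeing the data for giving 1 solution per gene. This held for 16040 genes in dendritic cells, 15809 in macrophages and 15160 in osteoclasts, 100% of those at or under the limit, within a relative tolerance of 8e-15. For Y-linked genes the limit was 700. On simulated reads 1000 of 1000 genes were recovered in each cell type and 0 wrongly. Whether 1 library had been read again and deposited under 2 labels was checked over the 18 pairs within a cell type. An exact copy could not reach this check, since the recovery needs 4 different size factors per cell type. Pairs across cell types were not examined. The chi-square per gene had a median from 1.19 to 3.56 and a mean from 3.92 to 13.95, where counting noise alone gives 0.455 and 1, so no pair looked like a repeat of the same library. This says nothing on whether the spread is biological. The libraries are named by letters within a cell type, since nothing ties one to a replicate number. These reads were tested with limma (voom weights) as an alternative chosen after seeing the data. In simulations of 9745 genes for osteoclasts against macrophages, 98% of 4-fold and 20% of 2-fold changes were called, with 6 unchanged genes called. Alternatives on the authors' values were no low-count filter, at least 1 CPM, upper-quartile scaling, totals made equal, adjusted p under 0.01 and at least 2-fold. The scalings shift the fold changes and keep the implied standard errors, which is an approximation. Other software was Python 3.11.15, numpy, scipy, pandas, statsmodels and numba.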

Results

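Gene expression was measured by RNA sequencing in 3 myeloid cell types grown from mouse bone marrow. Osteoclasts, the multinucleated cells that resorb bone, were grown with macrophage colony-stimulating factor (M-CSF, 30 ng/ml) and RANKL (50 ng/ml), macrophages with M-CSF alone (30 ng/ml), and immature dendritic cells with GM-CSF (20 ng/ml). Each cell type has 4 libraries, 12 in all. Per the labels the 3 cell types of an experiment came from 1 mouse, with 4 separate marrow extractions. The deposited values are the authors' mean normalised counts per cell type and their fold changes and p-values, so no standard deviation between libraries is given here. The authors' means sum to 2.42e+07 for osteoclasts, 2.50e+07 for macrophages and 2.77e+07 for dendritic cells. The size factors recovered for the 12 libraries ran from 0.975 to 1.04. Lyz2, which encodes lysozyme, was the most abundant gene in each cell type, with 1.87% of the summed means in osteoclasts, 2.79% in macrophages and 2.60% in dendritic cells. Throughout, a log2 fold change is given with the standard error implied by the authors' p-value (±), and a gene is called when the authors' adjusted p was under 0.05.

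Marker genes followed the labels. Ctsk (chromosome 3, 95499256 to 95509362 in GRCm38), the collagen-degrading protease of osteoclasts, had an authors' mean of 87805 in osteoclasts, 137 in macrophages and 1472 in dendritic cells in the authors' deposited table. The dendritic cell genes H2-Ab1 and Cd74, both of the class II antigen presentation pathway, had authors' means of 43679.7 and 237672 in dendritic cells against 488 and 3163 in macrophages in the authors' deposited table. The recovered macrophage libraries of H2-Ab1 ran from 121 to 1097 normalised reads, and their mean was 285 without library b. Csf1r, the M-CSF receptor, and Adgre1 (F4/80) had their highest authors' means in macrophages, 63822 and 42421, in the authors' deposited table.

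**Figure D1:**
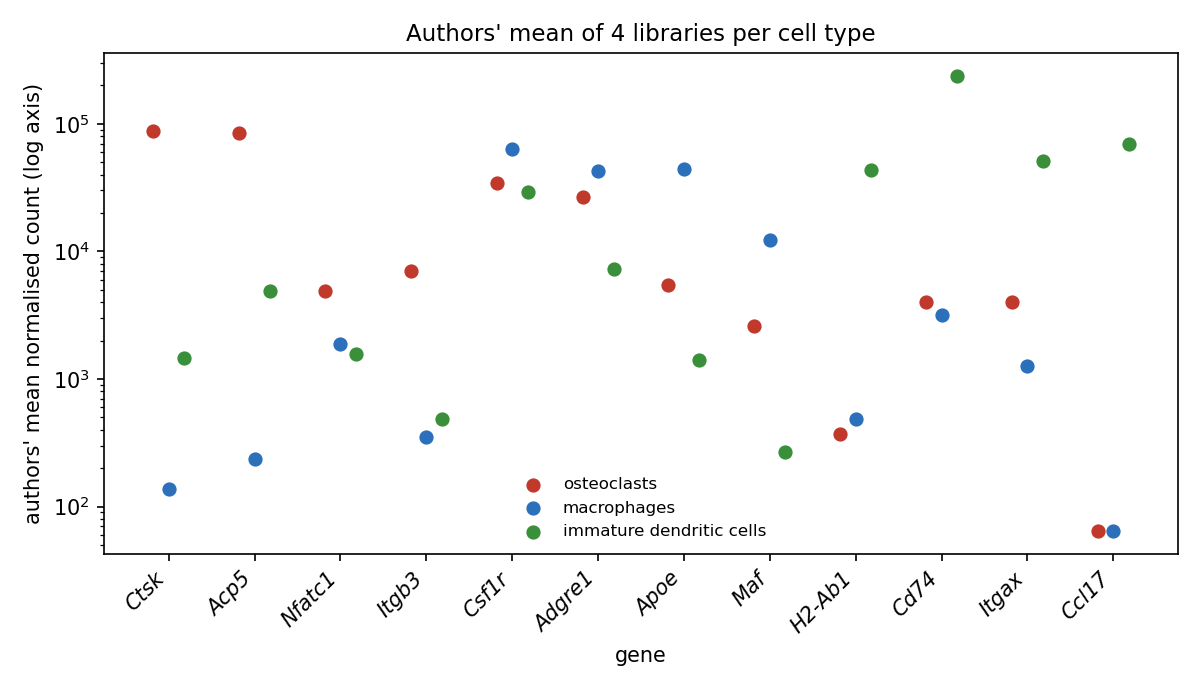
Authors' mean normalised counts (log axis) of 12 marker genes in osteoclasts, macrophages and immature dendritic cells, one point per cell type with no error because the authors deposited means of 4 libraries. Ctsk has a mean of 87805 in osteoclasts and 137 in macrophages.

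The first comparison asked which genes separate osteoclasts from the macrophages that share their precursor. Genes of bone resorption and osteoclast fusion were far higher in osteoclasts: Ctsk by 9.20 on the log2 scale, with a p listed as 0, Acp5 (tartrate-resistant acid phosphatase) by 8.36 ± 0.25 and Mmp9 by 8.47 ± 0.28 in the authors' deposited table. Nuclear genes of oxidative phosphorylation and genes of the tricarboxylic acid cycle were higher in osteoclasts, and macrophage markers and interferon-stimulated genes were lower. Of the tubulins, Tubb6 was 3.15-fold higher (log2 fold change 1.66 ± 0.30, adjusted p = 4.5e-07) in the authors' deposited table. In total 2593 genes were higher in osteoclasts and 2623 lower among the 17822 with an adjusted p in the authors' deposited table, of which 983 and 1165 differed at least 2-fold. Which direction held more genes depended on scaling: 2967 higher and 2342 lower (55.9% higher, against 49.7%) with the totals of the cell types made equal, and 2367 and 2824 (45.6% higher) under upper-quartile scaling.

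The osteoclast differentiation and fusion list had 14 of 18 members higher and 2 lower (14 and 2 adjusted over the list alone), and its median log2 fold change was 2.01. Ocstamp, needed for cell fusion, was higher by 6.54 ± 0.38 and Oscar, a co-stimulatory receptor, by 8.80 ± 0.42, while Trem2 fell by 0.78 and Adam8 fell by 0.73 in the authors' deposited table. On recovered reads the macrophage mean of Ocstamp went from 14.4 to 8.76 without library b. Calcr, the calcitonin receptor, had an authors' mean of 755 in osteoclasts and 0.243 in macrophages (1 read in all) in the authors' deposited table. All 13 members of the bone resorption list were tested and 11 were higher (11 adjusted over the list alone), among them Slc9b2 (3.84 ± 0.26) and Mmp14 (3.30 ± 0.34) in the authors' deposited table. Of 19 vacuolar ATPase subunits, which acidify the resorption lacuna, 14 were higher and 1 lower (15 and 1 adjusted over the list alone), with Atp6v0d2 at 2.48 ± 0.34 and Atp6v0a1 at −0.53 ± 0.15 in the authors' deposited table. The 3 lists were called higher in osteoclasts by limma's camera test, with adjusted p = 8.66e-21, 2.43e-57 and 5.86e-08. The podosome and actin list was not called (adjusted p = 0.0527, from 0.0146 to 0.374 over the alternatives, 3 of which called it). Of its 32 members tested 10 were higher and 5 lower (10 and 6 adjusted over the list alone). Itgb3, a vitronectin receptor subunit, was higher by 4.23 ± 0.30 and Src by 3.19 ± 0.31 in the authors' deposited table.

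Of the alpha and beta tubulins 4 of 13 tested were higher and 0 lower (6 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.118). Tubb6 (chromosome 18, 67390717 to 67402749 in GRCm38) had an authors' mean of 7270 in osteoclasts against 2256 in macrophages in the authors' deposited table. Tuba1c was higher by 0.86 ± 0.27 and Tuba4a by 0.95 ± 0.24, and Tubb3 had a mean of 3.99 against 0 in the authors' deposited table. The most abundant tubulin, Tubb5, did not pass the test, with authors' means of 26478 and 17641 and an adjusted p of 0.115 in the authors' deposited table. Tubulin-modifying enzymes were not called as a list (adjusted p = 0.61), with 2 of 21 higher and 5 lower (2 and 5 adjusted over the list alone). Nor were microtubule-associated proteins (adjusted p = 0.662), with 3 of 31 higher and 5 lower (3 and 5 adjusted over the list alone). Tubulin genes are similar in sequence, and how the authors assigned reads of 50 bases that match several of them is not given in the sources used here, so the values of single tubulins are uncertain.

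Nuclear genes of oxidative phosphorylation rose together, 61 of 77 higher and 0 lower (68 and 0 adjusted over the list alone, adjusted p = 3.88e-20). Their median log2 fold change was 0.53. Sdhd was higher by 0.82 ± 0.09 and Uqcrc2 by 0.81 ± 0.09 in the authors' deposited table. Of 25 genes of the tricarboxylic acid cycle, 22 were higher and 0 lower (23 and 0 adjusted over the list alone, adjusted p = 1.89e-15). None of the 12 mitochondrial genome transcripts tested was called (list adjusted p = 0.217, but the list was called higher on ranks, adjusted p = 0.0231), and mt-Co1 had authors' means of 141798 and 141852 in the authors' deposited table. The cell proliferation list was called higher (adjusted p = 0.0266, and adjusted p = 0.157 at a correlation of 0.05). Only 3 of its 31 members were called higher and 0 lower (0 and 0 adjusted over the list alone). Bub1, a mitotic checkpoint kinase, was higher by 0.98 ± 0.35 in the authors' deposited table.

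Macrophage markers were lower in osteoclasts in 16 of 20 cases and higher in 0 (17 and 0 adjusted over the list alone, adjusted p = 2.09e-12). Efferocytosis genes were lower in 11 of 14 (11 adjusted over the list alone, adjusted p = 1.49e-08). Fcgr1, the high-affinity IgG receptor, fell by 4.29 ± 0.38 and Apoe fell by 2.89 ± 0.41 in the authors' deposited table. The scavenger receptor Stab1 fell by 2.23 ± 0.35 and Gas6, a bridging molecule for dying cells, fell by 2.92 ± 0.29 in the authors' deposited table. Interferon-stimulated genes were lower in 17 of 25 cases and higher in 1 (19 and 1 adjusted over the list alone, adjusted p = 8.28e-07). Stat2 fell by 1.40 ± 0.20 and Mx1 fell by 1.62 ± 0.31, while Cxcl10 rose by 1.19 ± 0.33 in the authors' deposited table. Lysosomal hydrolases were lower in 10 of 29 and higher in 2 (12 and 3 adjusted over the list alone, adjusted p = 0.00235). Ctsb fell by 0.98 ± 0.09 in the authors' deposited table. Fcrls (2609 to 28.3) and Slco2b1 (279 to 1.75), both lower in osteoclasts, had the largest negative fold changes among the named genes, −6.23 ± 0.43 and −6.49 ± 0.59, in the authors' deposited table. B cell markers were lower (2 of 4 members, 2 adjusted over the list alone, adjusted p = 0.019), Ighm by a log2 fold change of −3.75 ± 0.47 in the authors' deposited table.

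Each gene list was compared with all other tested genes. In total 6 lists were called higher and 5 lower, and 24 were not called (adjusted p from 0.0527 to 0.9). Of the 24, 7 were called under at least 1 alternative: besides podosome regulators these were mitochondrial transcripts, glycolysis (lowest adjusted p = 0.0293) and T and NK cell markers (0.00159), all higher, and neutrophil (0.000949), erythroid (0.0187) and class II genes (0.0391), all lower. For inflammatory cytokines, stromal markers and plasmacytoid dendritic cell markers, none of them called, the median and the test had opposite signs. Over the alternatives the adjusted p ran from 4.84e-11 to 0.0558 for vacuolar ATPase subunits and from 0.000232 to 0.251 for lysosomal hydrolases, both lost with log2 fold changes as the statistic. It ran from 8.31e-05 to 0.157 for proliferation, also lost without genes under 1 CPM, and from 0.000199 to 0.0931 for B cell markers, lost on ranks and over all genes with a p-value.

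The second comparison set osteoclasts against immature dendritic cells. Osteoclast genes were higher and antigen presentation, dendritic cell and inflammatory genes were lower in osteoclasts. Tnfrsf11a, the RANKL receptor RANK, was higher in osteoclasts by 2.77 ± 0.16 and Ctsk by 5.83 ± 0.23, and H2-Ab1 fell by 6.33 ± 0.60 in the authors' deposited table. Among 21217 genes with an adjusted p in the authors' deposited table, 3554 were higher and 4275 lower in osteoclasts, and 1514 and 2836 of these differed at least 2-fold.

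The osteoclast differentiation list had 13 of 18 members higher and 0 lower (13 and 0 adjusted over the list alone, adjusted p = 1.96e-11). Bone resorption genes had 10 of 13 higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 2.1e-14). Mmp14, a membrane protease, fell by 1.58 ± 0.33, and Car2, a carbonic anhydrase, fell by 0.76 ± 0.32 in the authors' deposited table. The call of Car2 (adjusted p = 0.0435) was lost without the low-count filter, under upper-quartile scaling and with the totals of the cell types made equal, where its adjusted p reached 0.145. Ocstamp did not pass the test, with authors' means of 1589 and 2583 in the authors' deposited table. Oscar had an authors' mean of 2313 in osteoclasts and 7.15 in dendritic cells, and Slc9b2 was higher by 7.89 ± 0.32, in the authors' deposited table. Vacuolar ATPase subunits were called (10 of 19 higher and 2 lower, 10 and 2 adjusted over the list alone, adjusted p = 0.00258).

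Tubb6 was 2.31-fold higher in osteoclasts than in dendritic cells (log2 fold change 1.21 ± 0.30, adjusted p = 0.00023) in the authors' deposited table. Tuba1c (0.86 ± 0.27) and Tuba4a (0.65 ± 0.24) were also higher, and Tuba8 fell by 6.23 ± 0.57 and Tubb4a fell by 1.28 ± 0.32 in the authors' deposited table. The osteoclast mean of Tuba8 rests on 7 reads, and without library b it was 0.998 in place of 1.75. Of 14 tubulins 3 were higher and 3 lower (3 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.788).

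Class II antigen presentation genes were lower in 13 of 15 cases (13 adjusted over the list alone, adjusted p = 6.96e-22). Dendritic cell identity genes were lower in 15 of 17 with 1 higher (15 and 1 adjusted over the list alone, adjusted p = 1.02e-20). Maturation genes were lower in 14 of 16 (14 adjusted over the list alone, adjusted p = 3.26e-25). Mgl2, a C-type lectin, fell by 9.67 ± 0.27 and Irf4, a transcription factor, fell by 8.14 ± 0.34 in the authors' deposited table. Chemokines were lower in 12 of 20 and higher in 2 (14 and 2 adjusted over the list alone, adjusted p = 2.62e-12). Inflammatory cytokines and NF-kappa-B targets were lower in 13 of 20 and higher in 2 (13 and 3 adjusted over the list alone, adjusted p = 0.000133). Ccl6 fell by 6.21 ± 0.34 in the authors' deposited table. Cholesterol synthesis was lower in 19 of 23 with 1 higher (19 and 1 adjusted over the list alone, adjusted p = 5.04e-05). Glycolysis was lower in 15 of 21 with 1 higher (15 and 1 adjusted over the list alone, adjusted p = 0.000822), and lipid handling in 10 of 17 with 2 higher (11 and 2 adjusted over the list alone, adjusted p = 0.00696). Mvd, of the mevalonate pathway, fell by 2.59 ± 0.25 and Pfkp, a phosphofructokinase, fell by 2.22 ± 0.17 in the authors' deposited table. Proliferation genes were called higher (7 of 31, 3 adjusted over the list alone, adjusted p = 0.0388, and adjusted p = 0.194 at a correlation of 0.05). So was the tricarboxylic acid cycle (12 of 25 higher and 2 lower, 12 and 2 adjusted over the list alone, adjusted p = 0.018, and adjusted p = 0.106 at a correlation of 0.05). Nuclear genes of oxidative phosphorylation were not called (14 of 77 higher and 14 lower, adjusted p = 0.481). Nor were macrophage markers (8 of 20 higher and 4 lower, adjusted p = 0.428) or efferocytosis (5 of 15 higher and 5 lower, adjusted p = 0.644).

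Neutrophil markers were lower in osteoclasts than in dendritic cells in 13 of 14 cases (14 adjusted over the list alone, adjusted p = 2.2e-17), and mast cell and basophil markers in 10 of 10 (10 adjusted over the list alone, adjusted p = 5.43e-05). Eosinophil markers were lower in 7 of 8 and higher in 1 (7 and 1 adjusted over the list alone, adjusted p = 1.14e-11). Platelet markers were lower in 4 of 7 and higher in 1 (4 and 1 adjusted over the list alone, adjusted p = 0.00743). Ngp, a neutrophil granule protein, had an authors' mean of 0.747 in osteoclasts against 3031 in dendritic cells in the authors' deposited table. In total 5 lists were called higher and 12 lower, and 18 were not called (adjusted p from 0.145 to 0.788). Of the 18, 3 were called lower under at least 1 alternative: interferon-stimulated genes (lowest adjusted p = 0.0345), erythroid markers (0.0458) and stromal markers (0.0366). For the tubulins and the tubulin-modifying enzymes, not called, the median and the test had opposite signs. Over the alternatives the adjusted p ran up to 0.0937 for vacuolar ATPase subunits, 0.202 for glycolysis, 0.147 for cholesterol synthesis and 0.239 for the tricarboxylic acid cycle, each lost with log2 fold changes as the statistic, and up to 0.194 for proliferation; the last pair were also lost without genes under 1 CPM, and proliferation with the totals made equal. With the totals of the cell types made equal, all fold changes shift by 0.194, and the called genes divide into 5321 higher and 3341 lower (61.4% higher, against 45.4%) in place of 3554 and 4275.

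The third comparison set dendritic cells against macrophages, which were grown with different growth factors. Antigen presentation, dendritic cell and glycolysis genes were higher in dendritic cells and macrophage markers were lower. Ccl17, a chemokine, had an authors' mean of 69229.6 in dendritic cells and 64.9 in macrophages, and Folr2, a folate receptor, fell by 8.47 ± 0.30, in the authors' deposited table. Among 20730 genes with an adjusted p in the authors' deposited table, 4212 were higher and 3396 lower in dendritic cells, and 2645 and 1535 of these differed at least 2-fold.

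The 15 class II genes were higher in 14 cases and lower in 1 (14 and 1 adjusted over the list alone, adjusted p = 3.13e-17). Identity genes were higher in 14 of 17 and lower in 1 (15 and 1 adjusted over the list alone, adjusted p = 1.05e-20). Maturation genes were higher in 14 of 16 (14 adjusted over the list alone, adjusted p = 1.66e-25). H2-DMb2, of the class II list, rose by 6.38 ± 0.26, Zbtb46 by 5.97 ± 0.23 and Ccl22 by 8.68 ± 0.39 in the authors' deposited table. Cholesterol synthesis genes were higher in 21 of 23 with 1 lower (21 and 1 adjusted over the list alone, adjusted p = 4.5e-06), and glycolysis in 16 of 21 with 2 lower (16 and 2 adjusted over the list alone, adjusted p = 8.54e-06). Chemokines were higher in 10 of 20 with 1 lower (10 and 1 adjusted over the list alone, adjusted p = 6.9e-09), and inflammatory genes in 15 of 20 with 3 lower (16 and 3 adjusted over the list alone, adjusted p = 7.91e-07). Oxidative phosphorylation genes were higher in 53 of 77 with 1 lower (59 and 1 adjusted over the list alone, adjusted p = 2.66e-07). The tricarboxylic acid cycle was called (16 of 25 with 1 lower, 16 and 1 adjusted over the list alone, adjusted p = 0.0112, and adjusted p = 0.0809 at a correlation of 0.05). Lipid handling was called (11 of 17 with 2 lower, 12 and 2 adjusted over the list alone, adjusted p = 0.0388, and adjusted p = 0.131 at a correlation of 0.05). Il1rn, an interleukin-1 antagonist, rose by 4.88 ± 0.22 and Scd2, a fatty acid desaturase, by 4.35 ± 0.40 in the authors' deposited table.

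Bone resorption genes were called higher in dendritic cells than in macrophages, 5 of 13 with 4 lower (5 and 4 adjusted over the list alone, adjusted p = 0.00741). Ctsk rose by 3.37 ± 0.24, Acp5 by 4.31 ± 0.25 and Mmp14 by 4.88 ± 0.34, while Slc9b2 fell by 4.05 ± 0.32 and Plekhm1 fell by 1.15 ± 0.18 in the authors' deposited table. The osteoclast differentiation list was not called (adjusted p = 0.806), with 4 of 18 members higher and 5 lower (4 and 5 adjusted over the list alone): Ocstamp rose by 7.22 ± 0.38 and Fos fell by 2.71 ± 0.41 in the authors' deposited table. Without macrophage library b the mean of Ocstamp there was 8.76 in place of 14.4. Macrophage markers were lower in 15 of 20 with 1 higher (15 and 1 adjusted over the list alone, adjusted p = 1.82e-08), and efferocytosis in 9 of 15 with 3 higher (10 and 3 adjusted over the list alone, adjusted p = 3.97e-05). Lysosomal hydrolases were lower in 18 of 29 with 3 higher (19 and 3 adjusted over the list alone, adjusted p = 0.00114). Gas6 fell by 6.25 ± 0.29 and Stab1 fell by 4.76 ± 0.35, while Axl rose by 2.71 ± 0.68 and Mfge8, a bridging protein for dying cells, rose by 2.41 ± 0.39 in the authors' deposited table. Of 13 tubulins 4 were higher and 0 lower (4 and 0 adjusted over the list alone, adjusted p = 0.197, not called, but called higher on ranks, adjusted p = 0.0366). Tuba8 rose by 6.82 ± 0.63, with 4 reads in macrophages (mean 0.978, and 0.649 without library a), and Tuba1a by 1.21 ± 0.26 in the authors' deposited table.

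Markers of other cell types moved with the dendritic cultures. Neutrophil markers were higher in 12 of 14 and lower in 1 (12 and 1 adjusted over the list alone, adjusted p = 1.25e-13). Eosinophil markers were higher in 7 of 8 and lower in 1 (7 and 1 adjusted over the list alone, adjusted p = 4.17e-13). Mast cell and basophil markers were higher in 8 of 10 (9 adjusted over the list alone, adjusted p = 8.31e-05), and platelet markers in 4 of 7 (4 adjusted over the list alone, adjusted p = 0.00916). Ngp had an authors' mean of 3031 against 16.6 and Ear2 had 10435 against 10.4 in the authors' deposited table; on recovered reads the macrophage mean of Ngp was 10.8 without library c. Csf3r, the receptor for granulocyte growth factor, went the other way and fell by 1.38 ± 0.34 in the authors' deposited table. In total 15 lists were called higher and 3 lower, and 17 were not called (adjusted p from 0.0776 to 0.806). Of the 17, 6 were called under at least 1 alternative: tubulins, immediate early genes (lowest adjusted p = 0.0347), T and NK cell markers (0.00199) and stromal markers (0.00493), all higher, and microtubule-associated proteins (0.0348) and interferon-stimulated genes (0.0271), both lower. For B cell markers, not called, the median and the test had opposite signs. Over the alternatives the adjusted p ran up to 0.322 for bone resorption (on ranks), 0.433 for oxidative phosphorylation, 0.054 for glycolysis, 0.805 for the tricarboxylic acid cycle, 0.0702 for cholesterol synthesis and 0.109 for lysosomal hydrolases, all lost with log2 fold changes as the statistic, as was lipid handling (up to 0.131), also lost without genes under 1 CPM; the tricarboxylic acid cycle was also lost with the totals made equal (adjusted p = 0.0714). With the totals made equal, fold changes shift by −0.148 and the called genes divide into 3459 higher and 4623 lower (42.8% higher, against 55.4%) in place of 4212 and 3396.

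**Figure D2:**
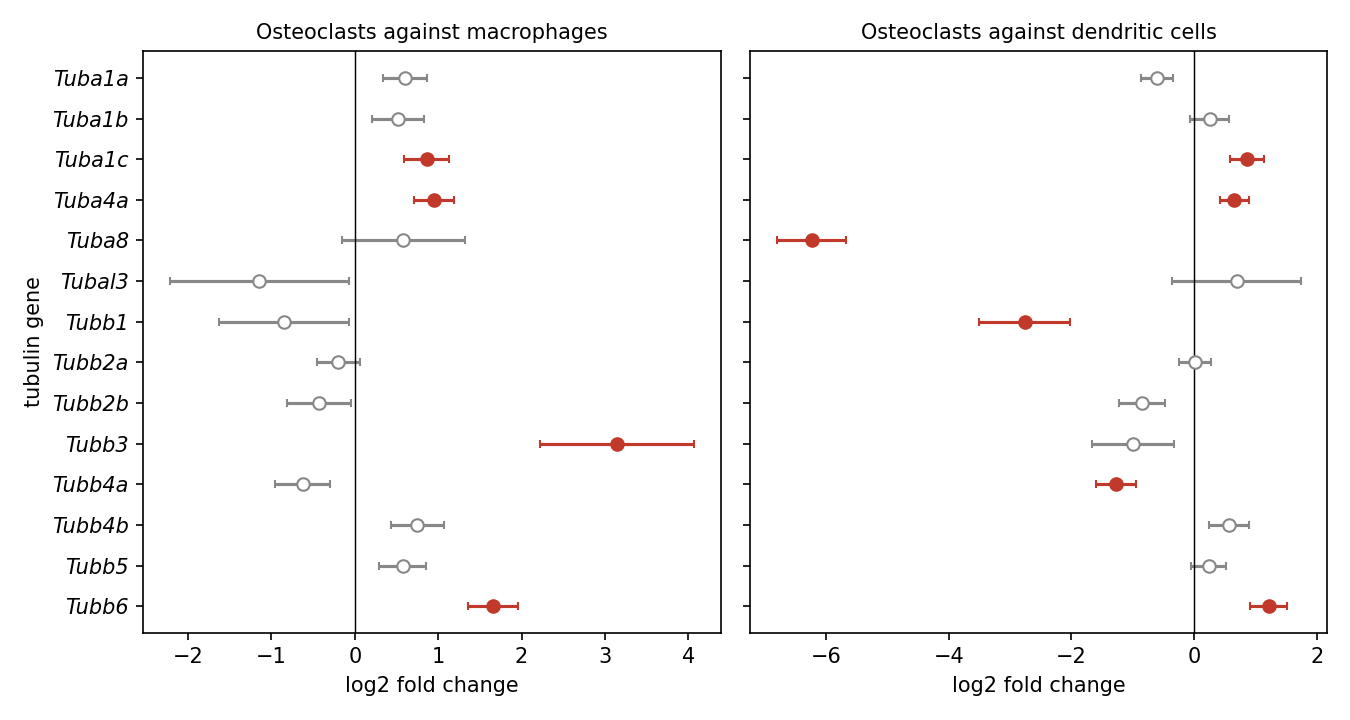
Log2 fold change of 14 tubulin genes in osteoclasts against macrophages and against dendritic cells in the authors' deposited table, with bars of 1 standard error implied by the authors' p-values and filled red points for adjusted p under 0.05. Tubb6 lies at 1.66 and 1.21, Tuba8 at −6.23 against dendritic cells, and Tubb3 had no counts in macrophages.

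Genes called at least 2-fold higher in one cell type than in both others numbered 444 for osteoclasts, 418 for macrophages and 2051 for dendritic cells. Independent lists of the same sizes would overlap by 83.5, 100.3 and 362 genes. Part of the excess over independent lists may come from the shared libraries. Simulated unchanged groups sharing these libraries overlapped by means of 6.12, 6.06 and 10.7 genes. No gene differed in that simulation, so data with many called genes were bound to exceed it, and it lends the overlaps no support. The 444 of osteoclasts include Dcn (283 against 1.21 and 1.53) and Mst1r (974 against 2.21 and 2.04), given as authors' means against macrophages and dendritic cells in the authors' deposited table. Dcn belongs to the stromal and osteoblast list, which was not called against macrophages (adjusted p = 0.415) or dendritic cells (adjusted p = 0.373, but called lower on ranks, adjusted p = 0.0366), and its member Pdgfrb had authors' means of 8.48, 2.66 in macrophages and 23.7 in dendritic cells in the authors' deposited table. The 418 of macrophages include Cd5l (12589 against 887 in osteoclasts and 260 in dendritic cells) and Slc40a1, the iron exporter (9318 against 500 and 322), in the authors' deposited table. The 2051 of dendritic cells include Aldh1a2 (3352 against 2.00 and 2.92) and Chil3 (56362 against 51.7 and 56.0), the order being osteoclasts and macrophages, in the authors' deposited table. Means this low rest on few reads: on recovered reads that of Mst1r was 0.649 without library a in macrophages and 1.02 without library d in dendritic cells, that of Dcn 0.682 without library c in dendritic cells, that of Pdgfrb 1.62 without library d in macrophages, and that of Aldh1a2 1.33 without library b in osteoclasts.

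**Figure D3:**
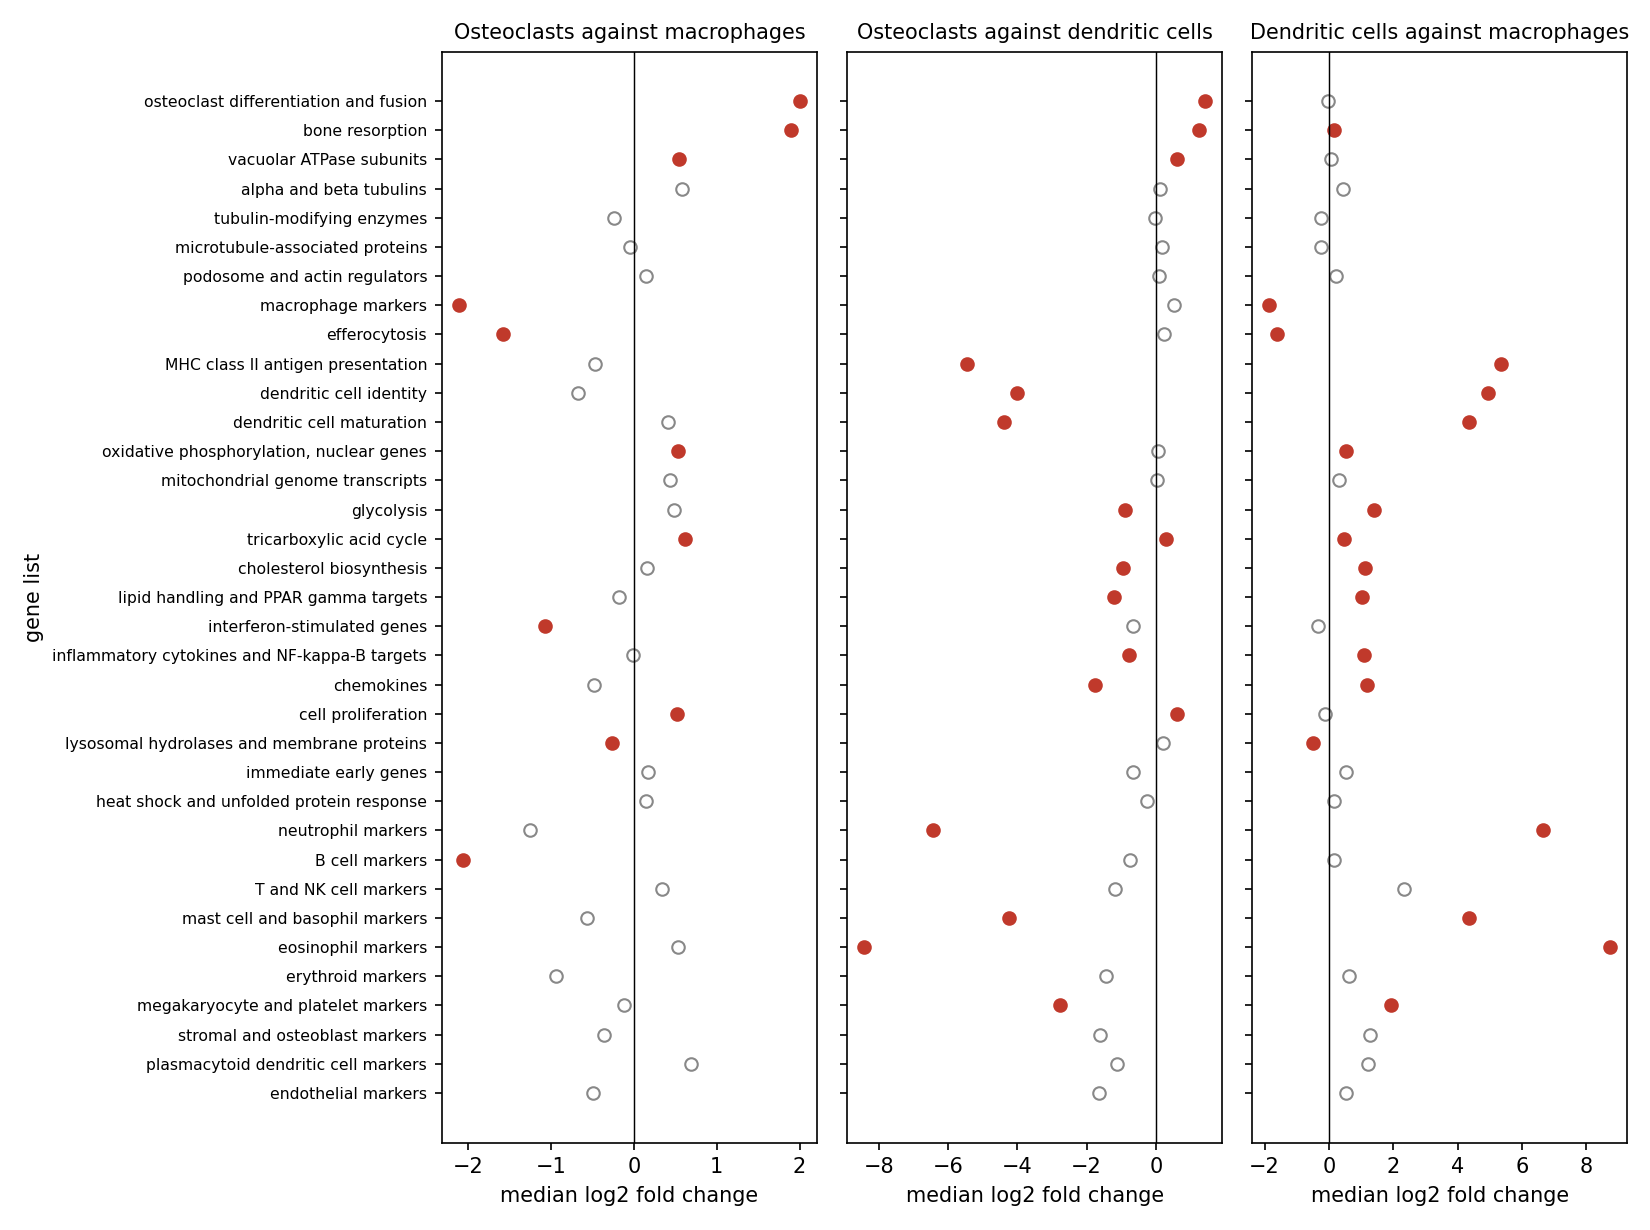
Median log2 fold change of the members of 35 gene lists in the 3 comparisons, whose axes have different ranges; filled red points are lists with adjusted p under 0.05 in limma's camera test on the authors' statistics. Class II antigen presentation has a median of 5.35 in dendritic cells against macrophages and bone resorption a median of 1.89 in osteoclasts against macrophages.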

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

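The test of Y-linked genes was chosen after their missing p-values were seen. For 227 sets of 4 values (224 gene and cell type pairs with a mean of at least 10 and 3 sets of size factors) the gap of the highest or lowest library to the nearest other was set against the range of all 4 (Dixon's ratio, against its 95% critical value). In 27 sets a library stood apart, 15 of them not Y-linked, where chance at 1 in 20 gives about 11.35 over all sets.

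Values below are normalised reads in the library that stood apart, with the others' range. In osteoclasts, library b was highest for Sncaip (85.1, others 41.3 to 46.7), Ccl4 (340.4, others 139 to 168), Cxcl10 (558.7, others 230 to 252), Ccr3 (329, others 196 to 216) and Camsap3 (232, others 119 to 138). Osteoclast library a was highest for Ighm (108.8, others 35.8 to 46.1) and Tppp3 (24.2, others 8.94 to 9.01), and library c for Ear2 (25.8, others 6.95 to 9.01) and Vash1 (60.6, others 26.0 to 31.8). In macrophages, library b was highest for Vegfc (90.6, others 21.6 to 29.7) and Ocstamp (31.2, others 7.67 to 10.8), library a for Ccr3 (186.7, others 101.3 to 114) and library d for Ccl17 (69.0, others 63.3 to 63.9). In dendritic cells, library d was highest for Il18 (240.1, others 144 to 160) and library b was lowest for Vash2 (14.3, others 25.6 to 27.5).

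The genes of the Y chromosome had most of their reads in 1 library of each cell type. Normalised reads in that library were 1389 (Ddx3y), 1631 (Eif2s3y), 613 (Kdm5d) and 490.4 (Uty) in dendritic cells, in library d. They were 2719.6 (Ddx3y), 1484 (Eif2s3y), 842 (Kdm5d) and 996 (Uty) in macrophages, in library b, and 1747 (Ddx3y), 1391 (Eif2s3y), 695 (Kdm5d) and 641 (Uty) in osteoclasts, in library d. The authors gave these genes no p-value. That 1 of the 4 mice of each cell type was male may explain it. The highest library held 88.0% to 99.8% of the reads of each gene in each cell type, and over 90% in 11 of 12 cases. The share was 88.0% for Kdm5d in dendritic cells, below the 90% set for the test, so the test as set leaves it open. There Kdm5d had 20, 28 and 34 reads in libraries a, b and c, against 602 in library d. It had 14 to 39 reads in each lower library of the other cell types. The labels give no sex. Which replicate it was cannot be told, no other explanation was tested, and traces in other libraries, such as 32.8 normalised reads of Ddx3y in osteoclasts, remain.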

How the results depend on the processing

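No paired analysis was possible because the table holds means per cell type and the recovered libraries carry no replicate number. The alternatives with totals made equal, ranks, log2 fold changes, a correlation of 0.05 and all those on recovered reads, including means without 1 library, were chosen after seeing the data. Of 132 counts under an alternative 120 stayed within 1.5 times their main value. A 2-fold requirement left 983 higher and 1165 lower genes (osteoclasts against macrophages), 1514 and 2836 (osteoclasts against dendritic cells) and 2645 and 1535 (dendritic cells against macrophages), by construction fewer. Lists called higher in osteoclasts against dendritic cells went from 5 to 3 at a correlation of 0.05, with log2 fold changes, without genes under 1 CPM and at adjusted p under 0.01; lists called lower in dendritic cells against macrophages went from 3 to 5 on ranks, and the cause was not tested. Of 46 list calls 30 held under each of the up to 7 other list tests at adjusted p under 0.05, and 0 reversed; of 59 list results without a call 16 gained one under at least 1 of these tests. Of 560 calls of named genes 45 were lost under at least 1 alternative and 0 changed direction. Calls of genes that the 1 CPM filter removed are not counted as lost: 532 of the 560 remained under it. Only the scalings could change a direction, since the other alternatives keep the fold change.

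On recovered reads of low genes, limma called 1553 genes for osteoclasts against macrophages, 3547 against dendritic cells and 3234 for dendritic cells against macrophages, and 808 of the first at adjusted p under 0.01. It kept 74.0%, 91.6% and 91.2% of the authors' calls among these genes, with 0 opposite. Leaving out each library gave 1110 to 1518, 3020 to 3446 and 2885 to 3079 genes, and leaving out the library of each type with most Y-linked reads gave 1110, 2924 and 2728. Of 35 splits of 8 libraries only the real one, 1 split, called as many genes, and the highest other called 19, 0 and 1. With libraries treated as unpaired, this argues against a chance split for the recovered genes. It cannot exclude chance, because 1 of 35 is the smallest share these splits can reach. The splits ignore shared mice, since only the library of each type with most Y-linked reads could be linked across types. Not run for want of values per library of high genes: the planned count tests and normalizations, replicate blocks, leave-one-out on the whole table, fry and an estimated correlation. Depth limits genes of few reads.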

Other observations

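The test of osteoclast shares, and limiting it and the shares of neutrophil reads to genes higher in dendritic cells, were chosen after the values were seen. Matching on the means of both cell types was added after reads per library had been recovered and before its result was known, and both matches had to agree for a verdict. Immediate early genes differed in opposite ways: Fos was 9998 in osteoclasts, 3318 in macrophages and 471 in dendritic cells, while Egr2 was 736, 222 and 7566, as authors' means in the authors' deposited table. Hspa1b, a heat shock gene, was 58.3, 14.6 and 17.4 in the authors' deposited table. Neither the immediate early list (adjusted p from 0.0776 to 0.483) nor the heat shock list (from 0.145 to 0.481) was called in the 3 comparisons, though over all genes with a p-value the first was called for dendritic cells against macrophages (adjusted p = 0.0347, up to 0.261 under other settings).

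Neutrophil transcripts were higher in dendritic cultures, with summed authors' means of 35969 against 1544 in macrophages and 610 in osteoclasts. Whether granulocytes remaining in numbers that vary between mice contribute is open. The implied standard errors of 12 neutrophil genes had a median of 0.622. This was at or above 100% of 10000 lists matched on the dendritic mean (95.9% when matched on both means). The medians of the matched lists were 0.227 and 0.494. These standard errors cannot decide the question, because they also carry the spread of the macrophage libraries. There the neutrophil gene Ngp ran from 2.88 to 34.1 normalised reads. A single library as the source is argued against, since the highest library held a median of 39.6% of the reads of 5 genes. Without Csf3r, which was lower in dendritic cells than in macrophages, the median of the other 4 was 39.8% (from 34.6% to 42.7%). The least abundant of these 4 had 66 reads in all. Dendritic library c was lowest for each of them, with 80, 68, 64 and 4 reads, where the highest libraries had 266, 348, 300 and 26. Csf3r was lowest in library a. The reads of these 4 genes, free of the macrophage spread, thus varied between dendritic libraries. They cannot tell varying numbers of granulocytes from varying transcription by dendritic cells. That dendritic cells themselves transcribe these genes stays open and was not tested.

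Of 31 osteoclast and bone resorption genes, 9 were higher in dendritic cells than in macrophages, 9 were lower and 13 were called neither way, and the 9 higher genes are weighed here. Osteoclasts formed in the dendritic cultures would bring the genes at 1 common share, but among 8 genes with a macrophage mean under 1% of the osteoclast mean the dendritic mean ran from 0.135% (Calcr) to 172% (Car2) of the osteoclast mean, a 1273-fold range. Calcr has few dendritic reads, but the 5 of these genes that were higher in dendritic cells still ran from 1.68% (Ctsk) to 172%, a 102.3-fold range. Ocstamp (162%) and Car2 make this range, which argues against osteoclasts as the whole source of their reads. Ctsk, Mmp9 (2.12%) and Acp5 (5.86%) lay closer together, so for them the range does not decide. Oscar, not among the 5, lay at 0.309%. A smaller contribution of osteoclasts is open. The test of whether a single dendritic library carries the reads of the 9 genes left it open. Their median standard error, 0.336, lay at 99.88% of lists matched on the dendritic mean. This alone would meet the bound of 95 first written, but it lay at 86.4% of lists matched on both means. The medians of the matched lists were 0.161 and 0.271. Such a percentile compares spread with other genes and does not give the share of 1 library. All 9 genes have a p-value, while the Y-linked genes, with most reads in 1 library, have none. If missing p-values mark such genes, this argues against 1 dendritic library holding nearly all of these reads. A larger part in 1 library is open.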
